A study of Mus musculus with 2 samples.

How the data were processed

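Gene expression was measured in M/E cells, mouse bone marrow cells immortalised by expression of the fusion gene MLL/ENL, with the genotype Mef2c del/-. Per the labels' protocols, a culture carrying an empty retroviral vector and a culture carrying a vector for a constitutively active Mef2c mutated in histone deacetylase binding (MEF2C-ASR) were selected with puromycin, seeded in fresh expansion medium and harvested after 6, 24 and 48 h. The medium held 10 ng/ml each of IL3, IL6 and GM-CSF and 100 ng/ml SCF. Total RNA of the 3 harvests was pooled per culture, amplified into Cy3-labelled cRNA and hybridised to an Agilent whole mouse genome array, so that each group is represented by 1 array and 1 pooled RNA. Per the file headers, both arrays lay on the same slide and were scanned together, so neither slide nor scan separated the groups.

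The deposited values are spot intensity values on a linear scale, made per the file headers with Feature Extraction 9.5.1.1. That software subtracted the background with spatial detrending, applied multiplicative detrending and replaced signals too dim to measure by surrogates. It also set the flags for spots well above background, saturated spots and outlier spots that were used here, per the file headers. No normalization between the arrays had been made. The deposited value table held 45018 intensity values per array, and its largest relative difference from the processed signals in the scanner files was 0, so its scale is the linear processed signal and no centring had been applied. The genome build of the probe coordinates is not given in the sources used here.

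Processed signals were converted to log2 and each array's 75th percentile over its 43379 non-control spots was subtracted. This percentile was a signal of 1272 on the control array and 1240 on the MEF2C-ASR array. Control spots and spots flagged as outliers on either array were left out (202 outlier spots on the control array and 201 on the MEF2C-ASR array), and spots of the same probe were averaged. A probe counted as measured where it was well above background and not saturated on both arrays, and no spot was saturated. The 41174 probes were named through a RefSeq gene table of the mouse assembly GRCm38.p6. Of these, 23082 were matched by accession, 6582 by symbol and 3073 by an older symbol, and the other 8437 kept the name in the file. A gene's value was the mean over its measured probes, which differed in sign in 1772 of the 5480 genes with more than 1 measured probe. Genes were counted as higher or lower only where all measured probes had the same sign, which left out 2 genes that were past 2-fold on average.

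With 1 array per group there is no replicate spread, so no test was run and no p-value is given. A rule of size was used in its place, a difference of at least 2-fold, or 1 on the log2 scale. Genes with no probe measured on both arrays, but with a probe well above background on 1 of them, were given a bound, the brighter level over the higher of the dim probe's own level and the lowest level well above background on the dim array. That lowest level was -5.05 on the control array and -5.96 on the MEF2C-ASR array, and levels below it are limited by background. The error from spotting was estimated from 150 probes printed 10 times, whose pooled standard deviation over spots was 0.12 on the control array and 0.09 on the MEF2C-ASR array (log2). A difference of a probe with 1 spot therefore carries a spotting error of 0.15, which leaves out the variation between cultures, RNA pools and labelling reactions. This value was pooled over probes well above background on both arrays and was not estimated by level. Signals of negative control spots had a standard deviation of 15.5 on the control array and 3.08 on the MEF2C-ASR array, so dim probes can carry a larger error. The number of arrays limits the precision of every value.

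The rule for size, the 34 gene lists and the rule for the genes named in the text were fixed before the data were examined. Named throughout are Mef2c, the other MEF2 family genes, Hprt, Hoxa9 and Meis1. Also named, among protein-coding genes with an official symbol and a mean level at or above the 25th percentile of measured genes, are the 15 with the largest difference in each direction, and the 8 with the largest bound in each direction. In each list up to 4 members at least 2-fold apart are named, or 2 members of highest level where none was. The lists of metalloproteinases, chemokine ligands and chemokine receptors were chosen with knowledge that the study had reported on these families. A list was summarised by the median difference of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn from 13441 genes matched on mean level in 20 bins. The percentile describes these 2 arrays and is not a test of the treatment.

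The steps were tested on simulated arrays with spotting noise only, in which 200 genes of the control against MEF2C-ASR comparison had been changed by known amounts. Of 16501 simulated genes, 0 unchanged genes passed 2-fold, which the small spotting noise made all but certain. Recovery was scored at 1.5-fold, a looser limit than the 2-fold rule, among changed genes measured on both simulated arrays. Of 46 such genes changed 2-fold, 97.8% were past 1.5-fold in the right direction, as were 100.0% of 44, 47 and 42 changed 3-, 4- and 8-fold. Changed genes not measured on both simulated arrays are left out of these shares. In the same simulation 6 of 100 random lists lay outside the central 95%.

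The alternatives were quantile normalization, scaling by the median, by the 75th percentile of probes well above background or by the E1A spike-in spots, removal of the intensity-dependent trend (lowess span 0.3), normexp background correction with offsets 0 and 50, the value table, all probes kept, the brighter probes alone (mean level above the median), outlier spots kept, the brightest probe or the median of a gene's probes, and thresholds of 1.5-fold and 3-fold. The normexp correction was fitted without spots flagged as background outliers, a choice made after seeing the data, because a speck on the control array gave 7 spots a local background over 100, up to 63509, where the median was 38. Leaving out the background-outlier spots from the main values, and fitting normexp on all spots, were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1 for normexp. Figures were drawn with matplotlib 3.10.9.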

Results

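Transcript levels were compared between 2 cultures of M/E cells, mouse bone marrow cells immortalised by the leukaemia fusion gene MLL/ENL, with the genotype Mef2c del/-. The control culture carried an empty retroviral vector, and the other carried MEF2C-ASR, a constitutively active form of the transcription factor MEF2C that is mutated in histone deacetylase binding. The comparison asks which transcripts differ when active MEF2C is put back into these cells. Each group was represented by 1 array with the pooled RNA of 3 harvests, so no difference has a replicate check, and "higher" and "lower" describe these 2 arrays. On the control array 26054 of 43379 spots (60.1%) were well above background, and on the MEF2C-ASR array 29283 (67.5%) were.

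Granulocyte, monocyte, cytokine and chemokine ligand genes were higher as groups with MEF2C-ASR, with list medians between 0.45 and 0.65 on the log2 scale. Cholesterol synthesis genes were lower by a small amount (median -0.20). Among the named genes measured on both arrays, the largest differences upward were those of Thy1, S100a6, Clec4n and Trem2, each more than 10-fold. The homeobox gene Hoxa11 was 14.5-fold lower, a value from a spot with a background flag. Mef2c itself was 2.54-fold higher, with a signal of 795 on the control array and 1969 on the MEF2C-ASR array (log2 difference 1.35). This value came from a probe at chromosome 13, 80738124 to 80738183, in a genome build not given in the sources used here. A second Mef2c probe, at 80652493 to 80652552, was not well above background on either array, and with all probes kept the mean over both was 0.68, below 2-fold. The labels do not say which part of the gene was deleted or whether the vector's transcript holds the probe's sequence, so the value does not separate endogenous from introduced transcripts. The other family members differed by less than 1.5-fold, with log2 differences of 0.31 for Mef2a, -0.07 for Mef2b and -0.04 for Mef2d (0.11 with its brightest probe).

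Of 16573 genes measured on both arrays, 289 (1.74%) were at least 2-fold higher with MEF2C-ASR and 316 (1.91%) at least 2-fold lower. A difference of at least 4-fold was found for 43 of the higher and 46 of the lower genes. Most transcripts were alike on the 2 arrays, with 90.4% of genes within 1.5-fold and a correlation of 0.989 across genes, which are not independent replicates. Hprt, per the labels the reference transcript of PCR assays, differed by 0.02, and by -0.15 with spike-in scaling. Hoxa9 and Meis1, homeobox genes bound by MLL fusion proteins, differed by -0.09 and 0.27. Genes below the 25th percentile of level made up 95 of the higher and 214 of the lower genes. These dim counts are not comparable, because the lowest level well above background was -5.05 on the control array and -5.96 on the MEF2C-ASR array. A gene dim on the MEF2C-ASR array could count as measured and lower, while one equally dim on the control array was left out. With the brighter probes alone 100 genes were higher and 34 lower. With scaling by the spike-in spots the median difference of all genes was -0.20 in place of -0.03, and 203 genes were higher and 450 lower.

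Thy1, a surface glycoprotein of T cells, stromal cells and some progenitors, was 14.5-fold higher with MEF2C-ASR (signal 290 against 4095). S100a6, a calcium-binding protein, was 13.5-fold higher, Clec4n, the fungal recognition receptor dectin-2, 13.3-fold, and Trem2, a lipid-sensing receptor of macrophages, 11.3-fold. The chemokine Ccl2 was 7.01-fold higher, the formyl peptide receptor Fpr1 6.90-fold and the cytokine Il1b 6.84-fold. Among proteases, the aspartic protease Asprv1 was 6.15-fold higher, the lysosomal cathepsin Ctss 6.11-fold, the kallikrein Klk1b11 5.78-fold and the neutrophil collagenase Mmp8 5.37-fold (signal 1692 against 8860). The actin-severing protein Scin (6.35-fold), the arginase Arg2 (5.60-fold), Tex26 (5.29-fold) and Cd74, the invariant chain of MHC class II (5.07-fold), completed the 15 genes named in this direction. Each of these differences exceeds the pooled spotting error of 0.15 on the log2 scale, but the variation between cultures is not known. The pooled error can be too small for genes dim on the control array, such as Ccl2 and Scin (signals 66.7 and 76.5 there). Tex26 was below 2-fold when all probes were kept (0.94). Normexp at offset 50, which shrinks low signals, gave log2 differences of 2.84 for Trem2, 1.95 for Ccl2, 1.91 for Scin and 1.88 for Arg2. Asprv1 has no value without spots flagged as background outliers, and the Klk1b genes are closely related copies, so their probes cannot be assigned with certainty.

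In the other direction, Sgsm1 was 20.4-fold lower (signal 851 on the control array and 40.7 on the MEF2C-ASR array) and the LIM domain gene Pdlim3 17.5-fold lower. Hoxa11 was 14.5-fold lower (3700 against 249) and the zinc finger gene Mzf1 11.3-fold lower (5283 against 455). Chga, the granule protein chromogranin A, differed by -3.45 on the log2 scale. The protease inhibitor Serpinb9g was 10.2-fold lower, the growth factor Clec11a 9.66-fold, the retinol carrier Rbp4 7.12-fold, the cytochrome gene Cyp2a4 6.96-fold and Prps1l1 5.88-fold. Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, was 5.87-fold lower, F13a1, the A chain of coagulation factor XIII, 5.08-fold, and the steroid dehydrogenase Akr1c18 4.85-fold. Ryk and Echdc2 were 4.59-fold and 4.30-fold lower. Cyp2a4 and Cyp2a5 are closely related copies, as are the Serpinb9 genes, so it is uncertain which copy their probes measured. With all probes kept the log2 difference was -4.98 for Cyp2a4 and -4.80 for Pdlim3. Normexp at offset 50 gave -3.10 for Sgsm1, -2.98 for Pdlim3, -2.59 for Chga, -2.41 for Serpinb9g and -1.90 for Prps1l1. Hoxa11 and Echdc2 have no value without spots flagged as background outliers. Hoxa11, Mzf1, Chga and Clec11a each rest on a single probe, as do S100a6 and Clec4n.

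Other genes were well above background on 1 array alone. A bound of at least 2-fold was found for 83 of 2199 such genes on the MEF2C-ASR array and 163 of 168 on the control array. These counts are not comparable, because the lowest level well above background was -5.05 on the control array and -5.96 on the MEF2C-ASR array. A gene seen on the control array alone can owe most of a 2-fold bound to this gap. The largest bound upward was that of Zfp521, a zinc finger gene of early haematopoietic cells, at least 42.6-fold higher with MEF2C-ASR (signal 1590). It was followed by Agpat4 (at least 9.05-fold), the receptor Bmpr1a (7.61-fold), Capns2 (5.75-fold), the lipoprotein lipase Lpl (5.58-fold), the potassium channel gene Kcng3 (5.17-fold), the macrophage elastase Mmp12 (4.99-fold) and Jph1 (4.75-fold). In the other direction the milk protein gene Csn2 was at least 217-fold lower (signal 4445 in the control) and the cytochrome gene Cyp2a5 at least 179-fold lower (3660 in the control). The cation channel gene Trpc6 was at least 21.1-fold lower, the RNA-binding protein Lin28b 15.5-fold, Tcim 11.8-fold, the glycosyltransferase Mgat3 11.3-fold and Defb20 10.0-fold, and the matrix protein gene Lum was lower by a bound of -3.46. The spots of Csn2 and Mmp12 carry a background-outlier flag, so these bounds are lost when such spots are left out. With normexp at offset 50 the other bounds named here were smaller by over 1.5-fold, all still past 2-fold.

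**Figure D1:**
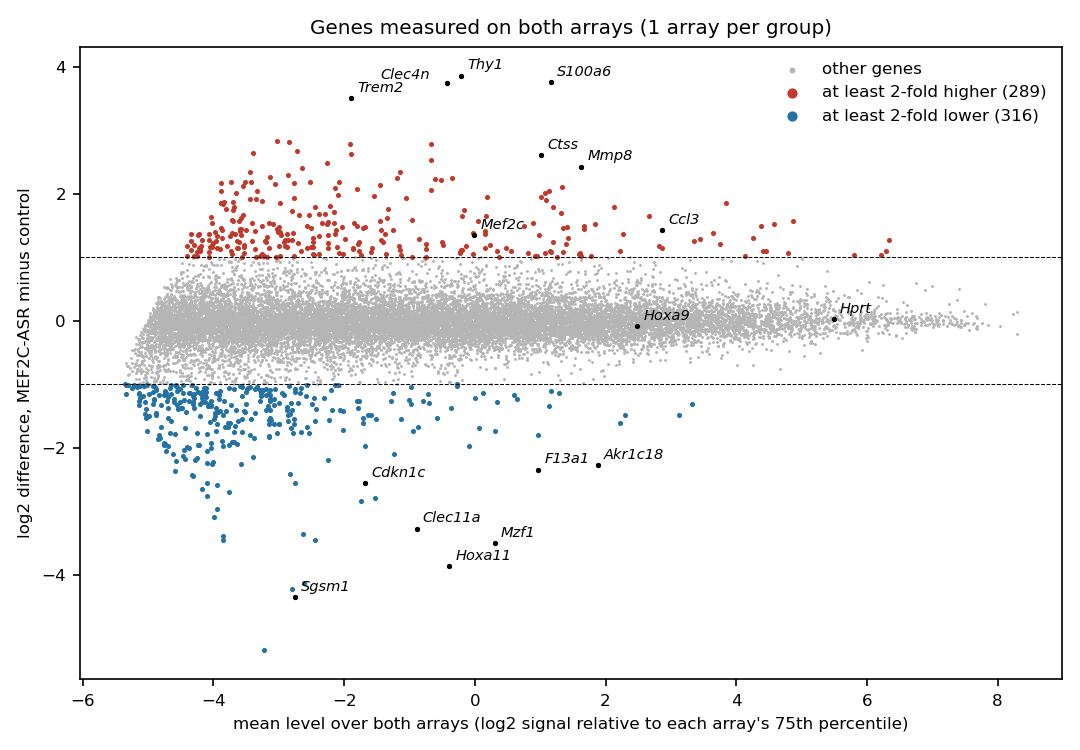
Log2 difference (MEF2C-ASR minus control) of each gene measured on both arrays against its mean level over the arrays, with dashed lines at 2-fold and 1 point per gene. The 289 higher genes reach into the brighter range, while 214 of the 316 lower genes lie below the 25th percentile of level. The lowest level well above background was lower on the MEF2C-ASR array, which lets in dim lower genes more readily than dim higher ones.

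Granulocyte and monocyte genes were higher as groups, with medians above those of all 10000 random lists of the same size and level. All 24 measured granulocyte genes had a difference above 0 in the main setting, with a median of 0.54, and 7 were at least 2-fold higher. Examples of these 7 besides Fpr1 are the decoy receptor Il1r2 (2.04), the resistin family member Retnlg (1.49) and the antimicrobial peptide gene Camp (1.44). Spike-in scaling lowers every difference by 0.17, which puts some of the 24 below 0, such as Ctsg (0.02) and Cd177 (0.02). It also puts some of the 7 below 2-fold, such as Mpo (0.94). In the monocyte and macrophage list 19 of 23 measured genes lay above 0, with a median of 0.65 (0.32 with all probes kept), and 8 were at least 2-fold higher, among them the scavenger receptor Msr1 (2.64; 1.67 with normexp at offset 50 and 3.64 with all probes kept) beside Clec4n, Trem2 and Ctss. In the dendritic cell and MHC class II list the median over 14 genes was 0.29 (percentile 99.97, and 93.9 with the brighter probes alone). Cd74 and the transcription factors Batf3 (1.24) and Relb (1.07) were at least 2-fold higher there, and Irf4 was higher by a bound of 1.13. The MHC class II genes of the list, named after their values were seen, did not follow Cd74. H2-Ab1 (0.32), H2-DMa (0.27), H2-DMb1 (0.27) and H2-Eb1 (-0.62) were within 2-fold, and H2-Aa was not well above background. Relb and the bound of Irf4 were below 2-fold with spike-in scaling, and Batf3 and Irf4 with normexp at offset 50.

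Of the other lineages, the markers of mast cells, basophils and eosinophils alone lay outside the central 95% of random lists in the main setting, and 3 further lists did so in another. For the 16 mast cell, basophil and eosinophil genes the median was 0.11 (percentile 98.2; -0.06 with spike-in scaling; percentile 96.8 with all probes kept) and the mean -0.06. Its members past 2-fold were lower, Il1rl1 by a log2 difference of -1.32 (below 2-fold with normexp at offset 50) and Prg3 by at least 2.54-fold (below 2-fold with normexp), and Il1rl1 stood at 0.02 when all probes were kept. For 18 stem and progenitor genes the median was 0.03 (percentile 82.3), and it was below 0 with spike-in scaling and with the percentile of probes well above background, but 0.21 at percentile 99.2 with the brighter probes alone. Ly6a, the Sca-1 antigen, was lower there (-1.53), and Procr was higher by a bound of 1.51, below 2-fold with normexp at offset 50. The median of 13 megakaryocyte and platelet genes was 0.06 (88.9), below 0 with spike-in scaling, and the platelet chemokine Pf4 was higher (1.24). The median of 11 erythroid genes was -0.10 (33.0) with none past 2-fold, and the brightest, Tfrc and Tspo2, stood at -0.36 and -0.19. For 13 B lineage genes it was -0.14 (19.8), with Bank1 lower (-1.63) and Cd79a higher (1.15), the latter below 2-fold with spike-in scaling and with normexp. For 12 T and NK lineage genes the median was -0.14 (24.2) and the mean 0.12, and with all probes kept the median was -0.48 at percentile 0.71. Thy1 was higher there, Zap70 lower (-1.65; below 2-fold with normexp at offset 50) and Gata3 lower by at least 2.31-fold (below 2-fold with normexp). For 11 stromal and endothelial genes the median was -0.08 (40.8) and the mean 0.24, and with all probes kept the median was -0.43 at percentile 1.80. Bounds included, 3 members were at least 2-fold higher, Thy1, Lpl and fibronectin (Fn1, a bound of 2.05, smaller by over 1.5-fold with normexp at offset 50), and 3 lower, Lum and 2 named after their values were seen, Pdgfrb (-1.81) and Mgp (at least 3.28-fold).

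Cytokine and chemokine genes were also higher. The median of 18 measured cytokine and NF-kB response genes was 0.63, above all random lists, with Il1b, Il12a (1.80), Tnf (1.09) and Relb at least 2-fold higher, of which Tnf and Relb were below 2-fold with spike-in scaling. Of 16 measured chemokine ligands, 6 were at least 2-fold higher, and 2 more were higher by a bound. Their median was 0.45, above all random lists, and 0.07 with all probes kept. Ccl3 and Ccl4, macrophage inflammatory proteins, were higher by 1.42 and 1.90, and Cxcl3, a neutrophil attractant, by a bound of 1.81. The median of 12 measured chemokine receptors was 0.28 (percentile 99.92). Ccr2 (1.42) and Cxcr2 (1.22) were at least 2-fold higher among them, and Cxcr2 was below 2-fold with normexp at offset 50. The matrix metalloproteinases did not stand apart as a group in the main setting, with a median of -0.01 and a mean of 0.33 over 9 measured genes (percentile 67.3), and the median was above 0 with median scaling or the intensity trend removed. It was also above 0 with all probes kept, at 0.15 and percentile 99.6. Mmp8 was the single member measured on both arrays past 2-fold, while Mmp12 and Mmp25 were well above background with MEF2C-ASR alone, with bounds of 2.32 and 1.93. The bounds of Mmp25 and Cxcl3 were smaller by over 1.5-fold with normexp at offset 50, still past 2-fold. The metalloproteinase and chemokine lists were chosen knowing that the study had reported on them and are not independent evidence. For 18 genes of ADAM proteases, the urokinase system and inhibitors the median was 0.07 (percentile 95.9) and below 0 with spike-in scaling. This list left the central 95% both ways, at percentile 1.13 with all probes kept (median -0.36) and at 99.99 with the brighter probes alone (0.51), and it lay above it with normexp too. Adam8 was higher (1.31) and Adamts5 lower (-2.37; -1.12 with normexp at offset 50) there.

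**Figure D2:**
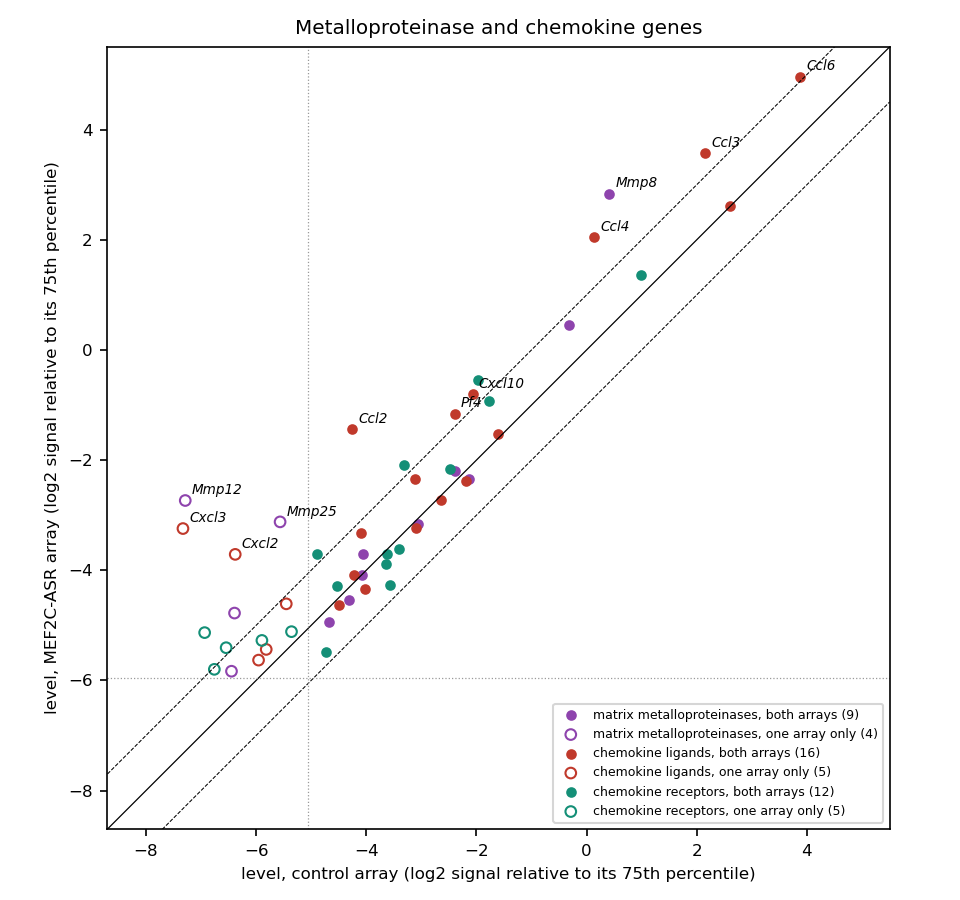
Level of each metalloproteinase and chemokine gene on the control array (horizontal) and the MEF2C-ASR array (vertical), as log2 signal relative to each array's 75th percentile, with dashed lines at 2-fold and dotted lines at each array's lowest level well above background. Filled points were measured on both arrays and open points on 1 array alone; labelled metalloproteinases and ligands are at least 2-fold higher, measured or by bound, and no gene lies past 2-fold below.

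Adhesion, survival and signalling genes differed by less. For 24 genes of the receptors for the growth factors in the medium and their signalling the median was 0.24, above all random lists. Socs3 and Cish, feedback inhibitors of cytokine signalling, were 2.91-fold and 2.15-fold higher there, and Cish was below 2-fold with spike-in scaling. The median of 16 BCL2 family genes was 0.23 (percentile 99.93), with none past 2-fold and Mcl1 at 0.25 and Bax at 0.08 (below 0 with spike-in scaling). It was 0.14 for 30 integrins and adhesion receptors (99.93; 95.2 with the brightest probe), and -0.02 with spike-in scaling, with no measured member past 2-fold and Itgb8 lower by at least 3.19-fold, below 2-fold with normexp at offset 50. For 30 genes of actin and motility it was 0.06 (92.6), below 0 with spike-in scaling and up to percentile 98.4 with the brightest probe, and the GTPase gene Rhoc was higher (1.91; 1.24 with normexp at offset 50). The median of 21 immediate early genes was 0.14 (99.1), and -0.03 with spike-in scaling. Egr1 (2.19; 1.36 with normexp at offset 50) and Ier3 (1.06) were at least 2-fold higher and Egr3 was higher by a bound of 1.63, and Ier3 was below 2-fold with spike-in scaling and Egr3 with normexp at offset 50.

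Genes tied to MEF2 itself showed little difference as groups. Egr1 was the single gene past 2-fold among 10 measured MEF2 targets outside muscle, whose median was 0.07 (percentile 89.5) and was below 0 with spike-in scaling, with all probes kept and with the brightest probe. For 20 muscle genes, many of them classical MEF2 targets, the median was -0.11 (26.2) with none past 2-fold, and it was above 0 with the brighter probes alone. The brightest, Smyd1 and Tagln, differed by 0.00 and -0.36, and Tagln by 0.13 with all probes kept. Over the 4 MEF2 family genes the median was 0.14 (85.4; below 0 with spike-in scaling). It was -0.06 over 9 class IIa histone deacetylases and MEF2 partners (31.7), where the brightest, Mapk14 and Hdac5, stood at -0.06 and 0.06 (Hdac5 below 0 with spike-in scaling). Whether targets of MLL fusion proteins stood apart as a group depended on the probes used. Their median over 24 measured genes was 0.02 and the mean -0.02 (77.2), and the median was below 0 with quantile normalization, the percentile of probes well above background and spike-in scaling. With the brighter probes alone it was 0.15 at percentile 99.4, and with the brightest probe of each gene it also lay above the central 95% of random lists. Within that list Mef2c and Zfp521 were higher and Hoxa11 lower.

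The medians of cholesterol synthesis and proliferation genes lay below the central 95% of random lists in the main setting. For 24 genes of cholesterol synthesis the median was -0.20 (percentile 0.01), with 20 of them below 0 and none past 2-fold, and the brightest, Ebp and Pmvk, stood at 0.12 (below 0 with spike-in scaling) and -0.34. For 30 proliferation genes the median was -0.09 (1.76; 2.61 without background-outlier spots), with 24 below 0 and none past 2-fold. The replication genes Mcm6 and Pcna stood at 0.04 and -0.19, and Mcm6 was below 0 with spike-in scaling and with the percentile of probes well above background. For 16 histone genes the median was 0.14 (98.6; 96.5 with the brighter probes alone) and -0.03 with spike-in scaling, with H2az1 at 0.02 and H3f3a at 0.11, both below 0 with spike-in scaling. H2az1 stood at -0.85 with all probes kept and has no value without spots flagged as background outliers. Of 34 lists, 12 lay above the central 95% of random lists and 2 below it. By chance 1.7 would be expected outside if the genes within a list varied independently, as randomly drawn genes do. Members of a list can vary together, and then any difference between 2 cultures puts more lists outside, so the counts do not measure an effect of MEF2C-ASR.

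The remaining lists lay within the central 95% of random lists in the main setting. The median of 22 cyclins, inhibitors and p53 targets was 0.08 (percentile 95.1; below 0 with spike-in scaling), and Cdkn1c alone was past 2-fold. It was 0.02 for 19 interferon-stimulated genes (80.1), below 0 with spike-in scaling and with the percentile of probes well above background, and 0.12 at percentile 98.6 with the brightest probe of each gene. There Ifi47 was higher (1.16), and Ifi44 and Iigp1 were lower by at least 2.11-fold and 2.21-fold, both below 2-fold with the intensity trend removed and with normexp at offset 50. It was 0.02 for 23 genes of the endoplasmic reticulum stress and amino acid response (72.7) and below 0 with quantile normalization and the same 2 scalings, and the cystine transporter Slc7a11 was 2.15-fold higher. Ifi47 and Slc7a11 were below 2-fold with spike-in scaling and with normexp at offset 50. For 25 genes of glycolysis and hypoxia the median was 0.00 (47.6), and carbonic anhydrase Car9 was lower (-1.13; below 2-fold with normexp at offset 50). For 16 reference genes the median was 0.01 (52.0) and the mean -0.03, and with 4 of 5 other scalings the median was below 0. Rplp0 and Rpl13a, the brightest of them, stood at 0.02 and 0.01, below 0 with the same 4. The 5 measured sex-linked genes, all on the Y chromosome, had a median of 0.11 (83.9; below 0 with spike-in scaling) with none past 2-fold, and Eif2s3y and Kdm5d stood at 0.11 and 0.01, both below 0 with spike-in scaling.

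**Figure D3:**
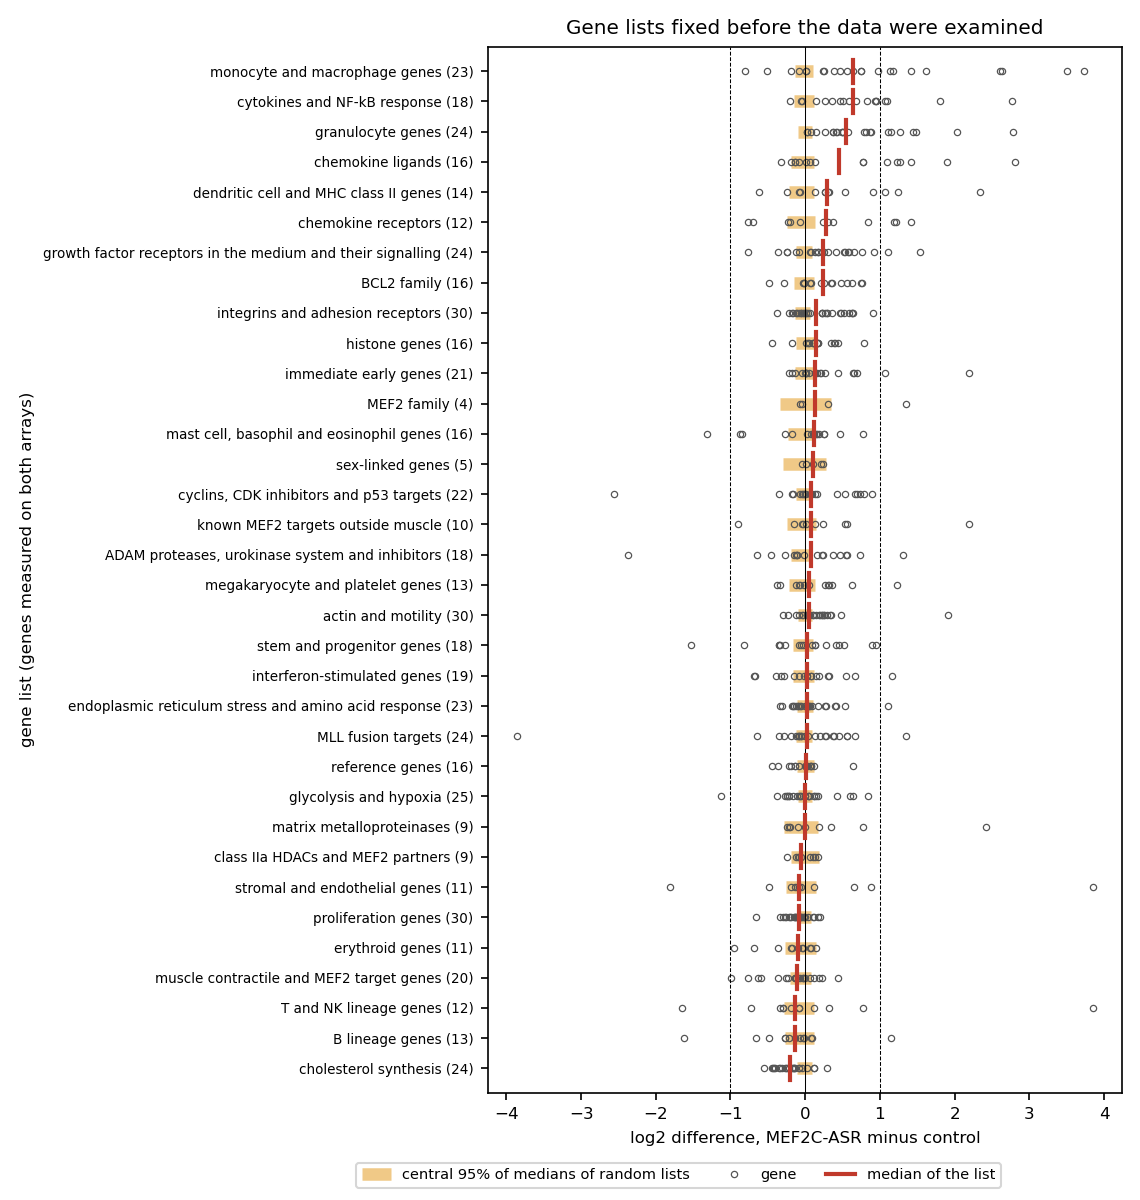
Log2 difference (MEF2C-ASR minus control) of the genes of each list measured on both arrays, with their number in brackets, the median as a red bar, the central 95% of medians of random lists as a shaded band and dashed lines at 2-fold. The medians of the monocyte and macrophage (0.65), cytokine (0.63), granulocyte (0.54) and chemokine ligand lists (0.45) lie above their bands and stay above 0 under each scaling tried, and that of cholesterol synthesis (-0.20) lies below its band.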

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

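All tests in this part were chosen after the results were seen, and each arm holds 1 culture.

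The spike-in spots, which hold synthetic E1A transcripts added to each labelling reaction and which the main values do not use, did not match after scaling. All 7 spike-ins well above background on both arrays were brighter on the MEF2C-ASR array, with a median difference of 0.17 on the log2 scale and a range of 0.04 to 0.21.

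Monocyte and macrophage genes were higher with MEF2C-ASR, with a median of 0.65 over 23 genes. Over 5 other scalings the lowest median was 0.48, where random lists of this size reached 0.10 at their upper bound in the main setting. Scalings by a single factor per array move this list and random lists alike, so this comparison cannot decide on array scaling. Random lists were matched on mean level, so quantile normalization and removal of the intensity trend also move this list and random lists nearly alike. The median still exceeded all random lists with both, an outcome close to fixed by the matching. What argues against an intensity trend as the cause is the main setting, where the median exceeded all random lists of matched level. Tissue macrophages with complement C1q mixed into the culture remain open, because the markers were picked from the same list after its values were seen. Of 10 markers, all members of the same list, 4 were measured on both arrays (C1qb, Apoe, Fcgr1 and Marco). Their differences were -0.51 to 0.00, the highest being that of Marco (0.0048), and 4 others were above background on neither array. C1qa and Siglec1 were above background on the MEF2C-ASR array alone, but their probes differed by only 0.04 and 0.40. On the control array these probes stood at -5.09 and -5.14, just under its lowest level well above background (-5.05), so the lower detection limit of the MEF2C-ASR array can account for these 2 calls. MEF2C-ASR and a difference between the cultures unrelated to it cannot be told apart with 1 culture per arm, and other monocytes or immature myeloid cells were not tested.

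A set of 29 protein-coding genes had a probe at least 8-fold apart between the arrays, bounds included, and 22 of them were lower with MEF2C-ASR. A faulty spot remains open for part of them. Of 13 genes with a second probe well above background on at least 1 array, 9 (69.2%) had every other detected probe at least 2-fold apart the same way. Among them were Cyp2a5, Sgsm1, Pdlim3, Serpinb9g, Agpat4, Trem2 and Thy1, while Cdcp1, Klra2, Braf and Slc16a6 did not show this. A second probe detected on 1 array alone was scored by a bound. For a lower gene, such as Sgsm1, the gap between the arrays' lowest levels (-5.05 and -5.96) gives most of a 2-fold bound, so agreement there was close to assured. For the 16 genes without a second detected probe, Csn2, Hoxa11 and Zfp521 among them, no value decides. Loss or gain of a chromosome segment would take neighbours along, and the 2 nearest measured genes on each side had a median of 0.02 in the direction of the gene (0.0192), with 6 of 116 neighbours past 2-fold. Neighbours seen on 1 array alone were left out, so a neighbour lost with its segment could not count. A median over all 29 genes also cannot decide for any single gene. A difference between the cultures unrelated to MEF2C-ASR, such as outgrowth of other clones, cannot be told apart from its effect with 1 culture per arm.

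Far more genes were above background on the MEF2C-ASR array alone (2199) than on the control array alone (168). A lower detection limit on the MEF2C-ASR array is a candidate explanation, since 96.2% of the 2199 genes lay within 2-fold of the control array's lowest detected level or below it, and 71.2% lay below it.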

How the results depend on the processing

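The alternatives that treat background-outlier spots in another way were chosen after seeing the data; the others were planned. Over the alternatives, the value table with its identical values included, 423 values of list medians moved by less than the spotting error of 0.15, 49 moved by more and 4 reversed (counted for lists outside the central 95% of random lists and genes past 2-fold), and for named genes these numbers were 1224, 246 and 1. The reversed list medians came with spike-in scaling, which shifted the median of all genes from -0.03 to -0.20, so that the shift itself accounts for them (integrins -0.022, mast cell genes -0.055, immediate early genes -0.029 and histone genes -0.026). Genes nearer 0, such as H2az1 and Tagln, also changed sign and are counted by size. The reversed gene was Il1rl1 with all probes kept (0.017), and the cause was not tested. Of 60 named genes past 2-fold on both arrays, 53 stayed past it with spike-in scaling, 59 with the brightest probe and 57 with all probes kept, and of the 57 that normexp gave a value, 54 did with offset 0 and 48 with offset 50. Csn2, Hoxa11, Asprv1, Echdc2, H2az1 and Mmp12 have no value with normexp, or without background-outlier spots, because their own spots carry that flag.

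Signal over background limits the counts, and the lower detection limit of the MEF2C-ASR array let in dim lower genes more readily than dim higher ones. The main counts were 289 higher and 316 lower (47.8% higher), with 83 and 163 genes by bounds. They were 155 and 115, and 17 and 54 by bounds, with normexp at offset 50, which shrinks low signals by construction. They were 790 and 981 with all probes kept, which also put 5 lists below the central 95% of random lists (ADAM, T and NK, stromal, proliferation and cholesterol), and 100 and 34 (74.6% higher) with the brighter probes alone, where the metalloproteinase, chemokine receptor, erythroid, T and NK and stromal lists held too few genes for a percentile. Spike-in scaling gave 203 and 450 (31.1% higher). At 1.5-fold they were 739 and 833, and at 3-fold 85 and 105. Of the genes measured on one array only, higher ones by bounds were 169 at 1.5-fold and 31 at 3-fold, and of genes measured on one array only, lower ones were 86 at 3-fold. Without background-outlier spots 1 list lay below the central 95%. Normexp fitted on all spots at offset 50 gave 6544 lower genes and 1 bound upward, where the fit without background-outlier spots gave 115 and 17. The monocyte, granulocyte and cytokine medians exceeded all random lists in each setting. The value table and scalings by a single factor per array cannot change a percentile. Quantile normalization and removal of the intensity trend can change it little, because random lists were matched on level. The lowest percentile over settings was 93.9 for dendritic, 95.2 for integrin, 96.5 for histone and 96.8 for mast cell genes, and the highest was 2.61 for proliferation and 0.26 for cholesterol genes. No paired analysis was possible because each group holds 1 array.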

Other observations

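The observations here were chosen after the values were seen. Among genes past 2-fold, those of highest level are least affected by background. The 10 brightest higher genes were led by S100a8 (2.41-fold, signal 66154 against 155457) and Mpo (2.15-fold), a calcium-binding protein and the peroxidase of neutrophil granules. They also held 4 stefin A genes, which encode inhibitors of cysteine proteases, with Stfa3 3.60-fold, Stfa2l1 2.95-fold, Stfa2 2.86-fold and Csta2 2.05-fold higher. These copies are closely related, so their probes cannot be assigned with certainty. Lyz1, the chemokine Ccl6, Cish and Adam8 completed the group, and 5 of the 10 stayed past 2-fold under all 5 other scalings. The 10 brightest lower genes all did, but spike-in scaling lowers every difference and so cannot take a lower gene back within 2-fold. The contrast with the higher genes therefore does not show that the lower ones are more robust. The 10 brightest lower genes included the heat shock gene Hspa2 (log2 difference -1.32), the apolipoprotein gene Apoc2 (2.79-fold lower), the cyclophilin gene Ppic (2.80-fold), the nucleosome-binding protein Hmgn1 (3.04-fold), the receptor Igf2r (2.53-fold) and the LIM gene Lmo1 (3.47-fold).

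Gene families grouped by the stem of the symbol were scanned for joint differences. Of 458 families with at least 4 genes at or above the 25th percentile of level, 6 had at least 3 members 2-fold higher and 0 had at least 3 members 2-fold lower. The kallikreins of the Klk1b group stood out, with 7 of 7 genes at or above that level higher by 1.37 to 2.53. None of these 7 was below 1.20 under the other scalings, and members of lower level were not counted. They lie together in the genome and are closely related, so the 7 values are not 7 independent measurements. In the S100a family S100a6, S100a4 and S100a8 were at least 2-fold higher among 8 genes at or above that level, with a median of 0.49 that stayed at or above 0.32 under the other scalings. The other families were Ifi, Ccl, Il and Cd, of which the Il and Cd medians (0.16 and 0.14) were below 0 with spike-in scaling.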
